A study of Mus musculus with 58 samples.

How the data were processed

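Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in mouse bone marrow-derived macrophages, cells grown from bone marrow for 6 days in medium with M-CSF, the macrophage growth factor. The cells were stimulated with 100 ng/ml lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4, for 0, 15, 30, 60 or 120 min. For each library 40 M cells were crosslinked with 4 mM DSG, a protein crosslinker, and 1% formaldehyde, per the labels' protocols. M stands for 1000000 throughout. The 9 targets were Brg1, CEBPb, CEBPd, Fos, JunB, JunD, ATF3, CREB and RelA, and RelA was measured in wild type and IRF3 KO cells. Of 58 samples, 55 had a peak list. The other 3 were input samples and were not analysed here on their own.

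Reads were processed with Bowtie2 and HOMER on the mouse build mm9, per the submitters' processing notes; versions were not given in the sources used here. Each peak list was called on 1 library against a control library, per the file headers, so that no list pooled replicates. The deposited values were used as they are, and the score and folds of a peak are the authors'. The signal is the normalized tag count of a peak, scaled by the authors to 10 M tags of the library, per the file headers. The score of each peak is the deposited peak caller score, used here only to rank or filter peaks. The fold over the control and the fold over the local background are ratios computed by the authors, and the lowest of either in any list was 4. In 22 lists the deposited tag column held counts of whole tags, among them all 10 CREB lists. In the other 33 lists the tags had been scaled to the control by the authors, per the file headers, and were read as signal. Coordinates are mm9 as deposited. The gene table at hand belongs to another assembly, GRCm38.p6, and no genome sequence of mm9 was used here, so that sites are given by coordinates alone and no gene or motif is assigned to them. The planned tests of gene lists and of motifs were therefore not run.

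Library sizes were taken from the ratio of whole tags to normalized tags or, in lists without whole tags, from the steps between low normalized values, a method that came within 0.250% of the known size in 17 lists that allow both. The libraries held 11.6 to 31.6 M tags. The control libraries differed in size between targets, from 12.6 to 43.4 M tags. The lists imply 8 control sizes over 1% apart, while the labels name 3 input samples, and which control served which list was not given in the sources used here. RelA lists of wild type cells were called against a control of 17.3 M tags and those of IRF3 KO cells against one of 12.6 M tags, which bears on peaks called in 1 genotype only. The most common peak width of a library ran from 178 to 386 bp, so that tags were counted over different widths in different libraries. Intervals on shares are Wilson 95% intervals and cover counting error only.

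Before the data were examined, groups were taken from the sample labels, and the comparisons, alternatives and the rule for named sites were fixed. CREB had 2 replicates at each time. The other 8 factors had 1 library per genotype and time. For RelA the design planned no test. After the data were examined, limma 3.58.1 was fitted to the log2 of the normalized tags plus 1 at the 13433 sites called in all stimulated RelA libraries, with genotype and time as additive terms and Benjamini-Hochberg adjustment at 0.05, which leaves 3 residual degrees of freedom. The spread is then the part of the genotype difference that varies between times, and the test cannot part genotype from anything else that differed between the 2 sets of libraries. No test was run over the times of the other factors. Nothing in the labels says that the CREB replicates came from separate cultures or animals, so that p-values measure only the spread between these samples, which may be technical. Peaks that overlapped by at least 1 bp counted as shared. Overlapping peaks of the libraries compared were merged into sites, and the strongest peak of each library gave its tags. For RelA a site stood apart if its log2 ratio of tags between genotypes was at least 1 in size with the same sign at all 4 stimulated times, or if it was called in 1 genotype at 2 or more stimulated times and in the other at none of them. For co-binding, chance overlap was the mean of 100 random shifts of the peaks along their chromosomes, with chromosome ends taken as the last base reached by any list.

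For CREB, the design planned limma on log2 normalized tags and, where the files hold counts, edgeR. Since they do, edgeR 4.0.16 in R 4.3.3 was used: its quasi-likelihood test on the whole tags at sites called in all 10 libraries, scaled by library size, with an F test over the 4 contrasts against 0 min and Benjamini-Hochberg adjustment at 0.05, and no block. limma 3.58.1 with a pseudocount of 1 or 10 and DESeq2 1.42.0, with its own scaling, were alternatives. The 2 replicates of a time were not copies of 1 library: the chi-square of their tags per degree of freedom was 1.67 at 60 min, the lowest of the 5 times, where copies would give about 1.

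The CREB test was tested on simulated data drawn from the real means, library sizes and site-wise dispersions, with 200 of 16070 sites changed at 120 min. Of 50 sites changed at each size, it recovered 0% at 1.5-fold, 8% at 2-fold, 76% at 3-fold and 88% at 4-fold, and it called 11 of 15870 unchanged sites. At 4 times the depth with the same dispersions it recovered 16% at 2-fold and 82% at 3-fold. The simulated tags varied independently at each site, with no shift shared by the sites of a library. The RelA test, on simulated data with the real residual spread, recovered 12% of 50 sites changed 1.5-fold, 70% at 2-fold and 98% at 3-fold, and called 2 of 13233 unchanged sites. These simulated libraries held no offset between genotypes shared by all sites, so that the false calls do not cover errors of scaling. The overlap and genotype rules recovered all 5 planted answers on simulated lists. Overlaps and counts were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

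The alternatives were a stricter score (at least 2 times the highest of the minimum scores of the lists compared), peak centres within 100 bp, an overlap of 50% of each peak, equal numbers of top peaks, centring on the median, a 1.5-fold limit for RelA, leaving out each time, and for CREB other scalings, tools, site definitions, a replicate block and leaving out each library. Sites were named by fixed rules: for each factor the 3 sites called only after stimulation with most tags at 120 min and the 2 called only at 0 min with most tags there; for RelA the 5 sites in each direction with the largest median ratio among those apart at all 4 times; for CREB up to 10 sites past 0.05, or the 3 with the smallest p where none passes. Sites on unplaced or mitochondrial sequence were left out of the naming.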

Results

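Binding of 9 factors was mapped by ChIP-seq in mouse bone marrow-derived macrophages at 0, 15, 30, 60 and 120 min of lipid A. Fos, JunB, JunD and ATF3 are AP-1 family proteins, CREB is a related bZIP factor, CEBPb and CEBPd are C/EBP factors, RelA is an NF-kB subunit, and Brg1 is the ATPase of a chromatin remodelling complex. RelA was mapped in wild type cells and in IRF3 KO cells, which lack a transcription factor of the interferon response. CREB had 2 replicates at each time. All other groups had 1 library, so that their values have no replicate error. RelA, with 2 genotypes at each time, was tested in a model in which the effects of genotype and time add up, and the times of the other factors were not tested. The 55 lists held 1912171 peaks, from libraries of 11.6 to 31.6 M tags (M, 1000000). The knockout itself could not be checked, since IRF3 was not measured.

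The first comparison asked how the bound sites of each factor differed over time. RelA differed most in the number of peaks: the wild type list held 1476 peaks at 0 min, 26090 at 15 min, 43869 at 60 min and 31146 at 120 min. JunB had 23672 peaks at 0 min, 30975 at 30 min, 59289 at 60 min and 60742 at 120 min. CEBPd had 7936 peaks at 0 min and 30364 at 120 min, and ATF3 had 21447 and 40503. CEBPb stayed between 17741 and 20275 peaks up to 60 min and had 30427 at 120 min. Fos had 37253 peaks at 0 min and 55204 at 60 min, and Brg1 had 36398 and 50340. JunD was already at 67261 peaks at 0 min and lay between 59993 and 68027 later. CREB had 32228 peaks at 0 min and 30252 at 120 min in replicate 1, and 38593 and 36245 in replicate 2.

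**Figure D1:**
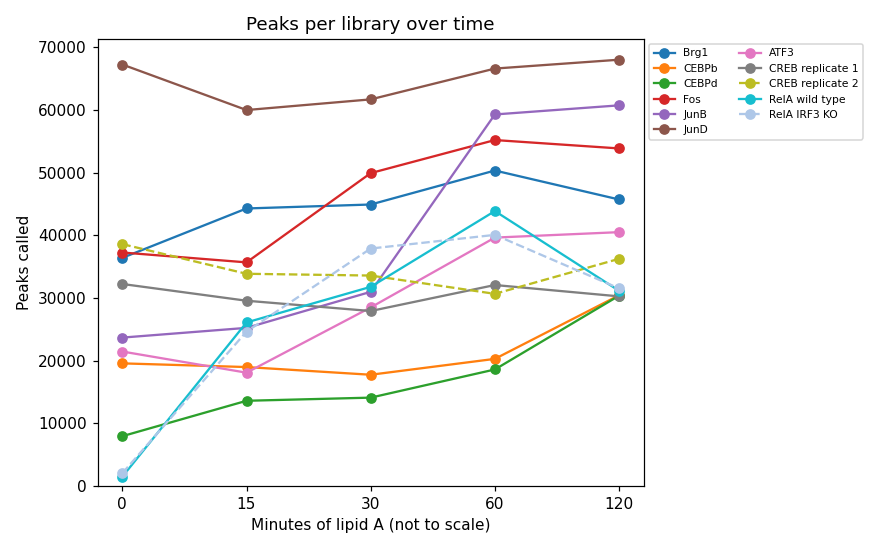
Number of called peaks (vertical axis) against minutes of lipid A (horizontal axis, not to scale), 1 point per library and 1 line per factor, replicate or genotype. RelA starts lowest, at 1476 and 2024 peaks, JunD is highest at each time, and JunB is at 60742 at 120 min.

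At the sites called at all 5 times, the median log2 ratio of 120 min to 0 min was 1.94 for JunB over 15282 sites (quartiles 1.44 and 2.44) and 1.79 for CEBPd over 5528 sites (quartiles 1.43 and 2.18). For RelA it was 1.79 over 883 sites in wild type (quartiles 1.37 and 2.34) and 1.78 over 1119 sites in IRF3 KO (quartiles 1.25 and 2.54). It was 0.74 for ATF3, 0.55 for CEBPb, 0.46 for Fos and 0.15 for Brg1. For JunD it was -0.25 over 41324 sites. For CREB it was -0.09 in replicate 1 and -0.41 in replicate 2, so that a shift of that size appeared between replicates of 1 factor. Tags were counted over peak widths that differed between times. The most common width ran from 178 to 360 bp over the wild type RelA lists and from 178 to 348 bp in IRF3 KO. For CEBPd it ran from 178 to 290 bp and for JunB from 222 to 282 bp. The narrowest were those of 0 min, so that width can raise the ratios of these factors. How far it does was not tested. JunB libraries had 3.13% of their tags in peaks at 0 min and 19.6% at 120 min, with 23.5 and 31.2 M tags. Of the JunB peaks of 0 min, 87.1% (95% interval 86.6 to 87.5) were called at 120 min, against 75.8% (75.5 to 76.1) for JunD, 74.3% (73.9 to 74.8) for Brg1 and 68.6% (68.1 to 69.1) for CREB replicate 1. With equal numbers of top peaks in the lists of a factor the order turned: the share was 62.4% for JunB, 65.4% for Brg1, 72.5% for CREB replicate 1 and 76.9% for JunD. Of the CEBPd peaks of 120 min, 23.0% (22.5 to 23.5) had been called at 0 min, or 54.0% with equal numbers. For RelA, 67.5% (65.1 to 69.9) of the wild type peaks of 0 min and 63.9% (61.8 to 65.9) of those in IRF3 KO were called at 120 min. These shares were 44.7% and 44.9% by an overlap of 50% of each peak, and 4.61% and 4.00% with equal numbers. The 50% rule is limited by width here, since a narrow peak of 0 min can hardly cover 50% of a wide one. By that rule 0% of the wild type peaks of 0 min were called at 15 min, so that it does not measure lost sites. With a stricter score the JunB ratio of 120 to 0 min was 5.52 instead of 2.57, the CEBPd ratio was 5.85 instead of 3.83, and the JunD ratio was 0.951 instead of 1.01. The RelA ratio was 248 instead of 21.1 in wild type and 60.9 instead of 15.6 in IRF3 KO.

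Some of the sites called only after stimulation with most tags were called for more than 1 factor. RelA had 1569.3 tags per 10 M at 60 min and 993.3 at 120 min on chromosome 11, 117807783 to 117808144, and IRF3 KO cells had 2090.8 and 1666.8 there. CEBPd was called at the same place, 117807702 to 117808021, with 80.7 tags at 15 min and 195.8 at 120 min. RelA was also called on chromosome 10, 37058114 to 37058474, with 765.6 tags at 15 min and 1559.5 at 60 min in wild type. A RelA site on chromosome 10, 18735077 to 18735449, had 1540.8 tags at 60 min. A site on chromosome X was called for CEBPd, 166413609 to 166413934, with 207.7 tags at 120 min, and for Fos, 166413618 to 166413940, with 148.3 tags. A site on chromosome 4 was called for ATF3, 144863754 to 144864075, with 197.5 tags at 120 min, and for JunD, 144863799 to 144864103, with 155.8 tags. JunB had 18 tags at 15 min and 305.6 at 120 min on chromosome 2, 102713461 to 102713788. ATF3 had 54.1 and 228.2 on chromosome 16, 84627369 to 84627677. CEBPb had 98.6 and 138.8 on chromosome 19, 10052230 to 10052644, and Brg1 had 32.2 and 72.7 on chromosome 2, 25405000 to 25405367. Calls of this kind depend on where the peak was centred: 10 of the 33 sites named as called only after stimulation, and 14 of the 22 named as called only at 0 min, had a peak of the same factor centred within 1 kb in a list they were missing from. Fos and JunD at chromosome 14, from 69891819 and 69891803, were such sites, with a peak of 0 min centred 498 and 516 bp away. CREB gave the clearest case: on chromosome 7 a site from 19813982 was called only at 0 min in replicate 1, and a site from 19813961 only at 120 min in replicate 2, with other peaks centred 592 and 608 bp away. Sites called only at 0 min with no such neighbour included 1 of Brg1 on chromosome 11, 59351903 to 59352225, with 37.4 tags, its nearest later peak lying 2769 bp away, and 1 of RelA in IRF3 KO on chromosome 9, 24346454 to 24346632, with 689 tags.

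The second comparison set RelA in wild type cells against RelA in IRF3 KO cells. At the stimulated times most RelA peaks were shared: 70.4% of wild type peaks (69.8 to 71.0) were overlapped in IRF3 KO at 15 min, 82.0% (81.6 to 82.4) at 30 min, 73.9% (73.5 to 74.3) at 60 min and 72.1% (71.6 to 72.6) at 120 min. Of the IRF3 KO peaks, 74.6% (74.0 to 75.1), 68.8% (68.3 to 69.2), 80.9% (80.5 to 81.3) and 71.2% (70.7 to 71.7) were overlapped in wild type. CREB replicates of the same time shared 70.6% to 86.1% of their peaks over both directions. With equal numbers of top peaks in both genotypes, from 24631 to 40068 by time, the RelA shares were 73.2%, 78.1%, 78.0% and 72.0%, and with 27914 peaks those of CREB replicates were 80.3% to 81.9%. With the stricter score the shares over both directions were 69.8% to 87.8% for RelA and 68.0% to 93.8% for CREB replicates. The RelA shares thus lay inside the range of the replicates with the stricter score, where list lengths differed. With equal numbers of top peaks they all lay below that range. As called, the 70.4% of wild type peaks at 15 min and the 68.8% of IRF3 KO peaks at 30 min also lay below the 70.6% of the replicates. At 0 min 27.2% (25.03 to 29.56) of the 1476 wild type peaks were shared, or 63.0% of the 211 left with the stricter score. Of the 2024 IRF3 KO peaks at 0 min 19.9% (18.2 to 21.7) were shared, or 17.8% of the 749 left with the stricter score. The wild type lists had been called against a control of 17.3 M tags and the IRF3 KO lists against one of 12.6 M tags. The median log2 ratio of IRF3 KO to wild type tags at shared sites was 0.12 at 15 min, 0.48 at 30 min, 0.04 at 60 min and 0.33 at 120 min. RelA tags were highest at 60 min at 83.5% of the 18533 wild type sites called at all stimulated times. In IRF3 KO, 46.2% of 18551 such sites were highest at 60 min and 39.6% at 30 min. These tags were scaled by library size, and a shift of 1 whole library can set the time of the highest value. The median log2 change from 30 to 60 min was 0.49 in wild type and 0.03 in IRF3 KO. It was taken at the 13433 sites called in all stimulated libraries. A difference in timing between the genotypes was not tested.

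At the 13433 sites called in both genotypes at all 4 stimulated times, limma with genotype and time as additive terms, fitted to log2 tags with Benjamini-Hochberg adjustment, found 3001 sites past 0.05 between the genotypes, with 5079 at an unadjusted p under 0.05. Of the 3001 sites, 96.1% were higher in IRF3 KO, where the median log2 ratio of all sites was 0.27. After centring on library medians 1430 sites passed, 60.7% of them higher, and after quantile normalization 1133, 47.0% of them higher, so that the balance between directions rested on the scaling. Without both libraries of 120 min 390 sites passed, and without those of 30 min 1315. In the same fit 10000 sites passed between the stimulated times, or 7571 after centring. With 1 library per genotype and time, the 2 genotypes stood in for replicates of a time. Time cannot be parted from anything else that differed between the libraries of different times. The model takes the course over time as the same in both genotypes. The median log2 changes from 30 to 60 min were 0.49 in wild type and 0.03 in IRF3 KO.

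Of these 13433 sites, 18 were at least 2-fold higher and 7 at least 2-fold lower in IRF3 KO at every stimulated time. After centring on the median ratio of each time the counts were 11 and 17, so that the balance between directions turned with the scaling. At a limit of 1.5-fold they were 112 and 21, and with the stricter score 8 and 5. The largest difference was on chromosome 7, 135272642 to 135273084, where wild type cells had 88.8 tags per 10 M and IRF3 KO cells 484.4 at 60 min, a median log2 ratio of 2.61 over the stimulated times. The other higher sites named were on chromosome 7, 38971649 to 38972260 (2.41), chromosome 11, 116527848 to 116528289 (2.03), chromosome 14, 64224330 to 64224973 (1.99) and chromosome 2, 51078488 to 51078952 (1.97). The lowest was on chromosome 3, 38001440 to 38001901, with 290.2 tags in wild type and 54.8 in IRF3 KO at 60 min and a median log2 ratio of -2.10. The other lower sites were on chromosome 19, 32030802 to 32031249 (-1.91), chromosome 14, 70424514 to 70424934 (-1.83), chromosome 17, 79499242 to 79499654 (-1.49) and chromosome 9, 105386582 to 105386955 (-1.35). A further 4269 sites were called only in wild type and 4000 only in IRF3 KO, each at 2 or more stimulated times, or 2019 and 2561 with the stricter score. These were mostly weak: their median highest value was 15.5 tags per 10 M, against 46.0 at 29291 sites called in both genotypes. The latter were called at 2 or more stimulated times in each genotype. Their highest value was taken over the libraries of both genotypes, which can raise it. Some of the sites called in 1 genotype only were tall. IRF3 KO had 592.3 tags at 30 min and 518.7 at 60 min on chromosome 10, 17507723 to 17508088. Wild type had 195 at 30 min and 281.7 at 60 min on chromosome 3, 83648610 to 83648992. Neither site was called at 15 or 120 min, even in its own genotype. Peaks near these tall sites were not looked at site by site.

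The third comparison asked whether CREB binding changed with time, the only one with replicates. Of 60209 CREB sites, 16070 were called in all 10 libraries and were tested. The edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment called 0 sites, with 2080 at an unadjusted p under 0.05. The count depended on the settings, among them the scaling. On tags scaled by library size, limma with a pseudocount of 1 also called 0 sites, and on quantile normalized values it called 230. DESeq2 called 435 with a scaling of its own, so that tool and scaling cannot be told apart there. edgeR called 184 after centring on the library medians, of which 83.2% had their largest change upwards, and 182 with TMM scaling. The direction was not settled: among sites at an unadjusted p under 0.05, 24.8% had their largest change upwards as scaled by library size, 59.7% after centring, and 61.2% as scaled by library size without replicate 2 at 0 min. The median log2 change of all sites at 120 min was -0.26 as scaled by library size and 0.01 with TMM. Leaving out each library in turn gave 0 sites each time. Replicate 2 at 0, 15 and 30 min stood apart from the other 7 libraries: 14.6%, 14.5% and 13.6% of their tags lay in peaks, against 9.54% to 11.2% in the others. Without those 3 libraries, a choice made after seeing the data, edgeR called 2606 sites, with the spread then estimated only from the replicates at 60 and 120 min, the 2 times whose replicates differed least. On simulated data the test found 8% of 2-fold and 76% of 3-fold changes, so that changes of 2-fold or less were mostly not detectable here. The simulated tags held no shift of whole libraries, so that the 76% may not carry over to the real ones. In the real data, sites with log2 changes of 1.98 and 2.05 at 120 min did not pass.

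The 3 sites with the smallest p did not pass. Chromosome 11, 49568734 to 49569118, had 19.4 ± 0.14 tags per 10 M (SD, n = 2) at 0 min and 84.8 ± 10.6 at 60 min. Chromosome 18, 75120834 to 75121232, had 14.5 ± 3.0 at 0 min and 60.3 ± 2.9 at 120 min. The edgeR adjusted p was 0.0704 for both, with log2 changes at 120 min of 1.98 and 2.05. Chromosome 13, 83711152 to 83711592, had 74.7 ± 2.5 at 0 min and 26.1 ± 2.5 at 120 min, with an edgeR adjusted p of 0.176 and a log2 change of -1.52. All 3 passed with DESeq2 and with TMM scaling, at adjusted p values of up to 0.0290. Over all alternatives their adjusted p ran from 2.54e-16 to 0.579.

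**Figure D2:**
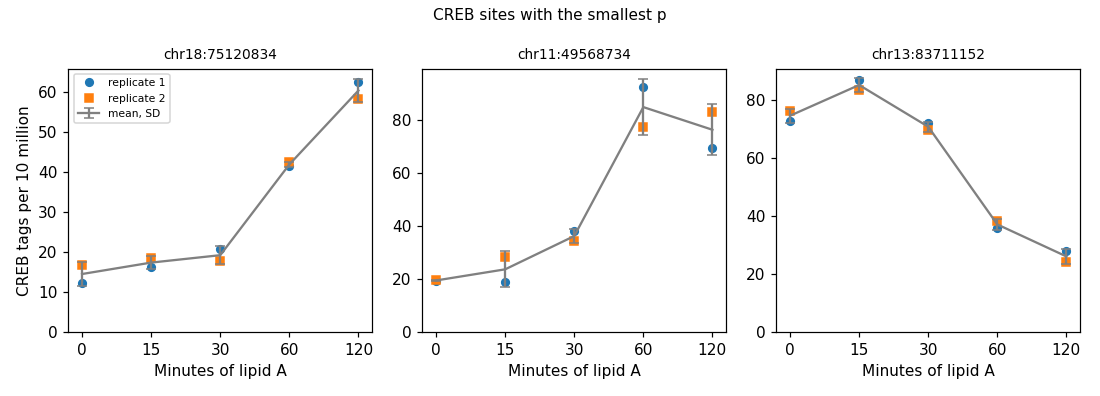
CREB tags per 10 M (vertical axis, a scale of its own in each panel) against minutes of lipid A (horizontal axis, not to scale) at the 3 sites with the smallest p, with both replicates as points and the mean with its SD (n = 2) as a grey line. Mean tags at the chromosome 18 site were 14.5 at 0 min and 60.3 at 120 min, and at the chromosome 13 site 74.7 and 26.1; none passed the test.

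CREB replicates also gave a spread between libraries of the same time, for CREB alone. Whether it holds for the other factors is not known. On average 78.4% of the peaks of 1 replicate were overlapped by the other at the same time (SD 0.772, n = 5 times, both directions averaged). Between different times the mean was 76.3% within a replicate and 74.8% across replicates. Across replicates, same-time shares lay 3.65 percentage points above those between times, more than in any other of the 120 orders of the times of replicate 2 (one-sided exact permutation test, p = 0.00833, the smallest they can give). With equal numbers of top peaks the difference was 3.80 points, at the same p.

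The last comparison asked which factors shared sites. Overlaps of all 90 ordered pairs of lists lay above each of 100 random shifts at both 0 and 120 min, with mean chance shares of at most 1.79%. The shifts move peaks to any place on a chromosome. They cannot part sites shared by particular factors from regions where peaks of any factor are frequent. At 0 min 92.8% of JunB peaks (92.5 to 93.1) were overlapped by JunD. At 120 min 86.7% of ATF3 peaks (86.4 to 87.1) and 82.6% of JunB peaks (82.3 to 82.9) were overlapped by JunD, as were 84.8% (84.4 to 85.2) and 83.9% (83.5 to 84.2) of CREB peaks in replicates 1 and 2. Fos overlapped 67.1% of JunB peaks (66.8 to 67.5), a share that was 40.5% with the stricter score. JunB overlapped 32.7% of JunD peaks (32.3 to 33.0) at 0 min, or 16.2% with the stricter score, and 73.8% (73.4 to 74.1) at 120 min. CEBPb overlapped 82.9% of CEBPd peaks (82.0 to 83.7) at 0 min and 69.7% (69.2 to 70.3) at 120 min, while CEBPd overlapped 33.6% and 69.6% of CEBPb peaks. The lists differed in length between the times. With equal numbers over all 10 lists, JunB overlapped 73.5% of the top 1476 JunD peaks at 0 min and 79.5% of the top 30252 at 120 min, and CEBPd overlapped 71.5% and 69.8% of the top CEBPb peaks. With 1 number of top peaks at both times, chosen after seeing the data, JunB and JunD shared 74.0% and 79.5% of 23672 peaks, and CEBPb and CEBPd 62.4% and 80.9% of 7936, which turned the direction of the CEBPd share. Of RelA peaks at 120 min, 79.5% (79.0 to 79.9) were overlapped by JunD, 68.6% (68.1 to 69.1) by Brg1 and 40.1% (39.6 to 40.7) by CEBPb. Among the top 1476 peaks of each list, the number of RelA peaks at 0 min and also chosen after seeing the data, these shares were 24.1%, 28.9% and 18.0%. The shares depend on the length of the other list, and JunD had the longest.

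**Figure D3:**
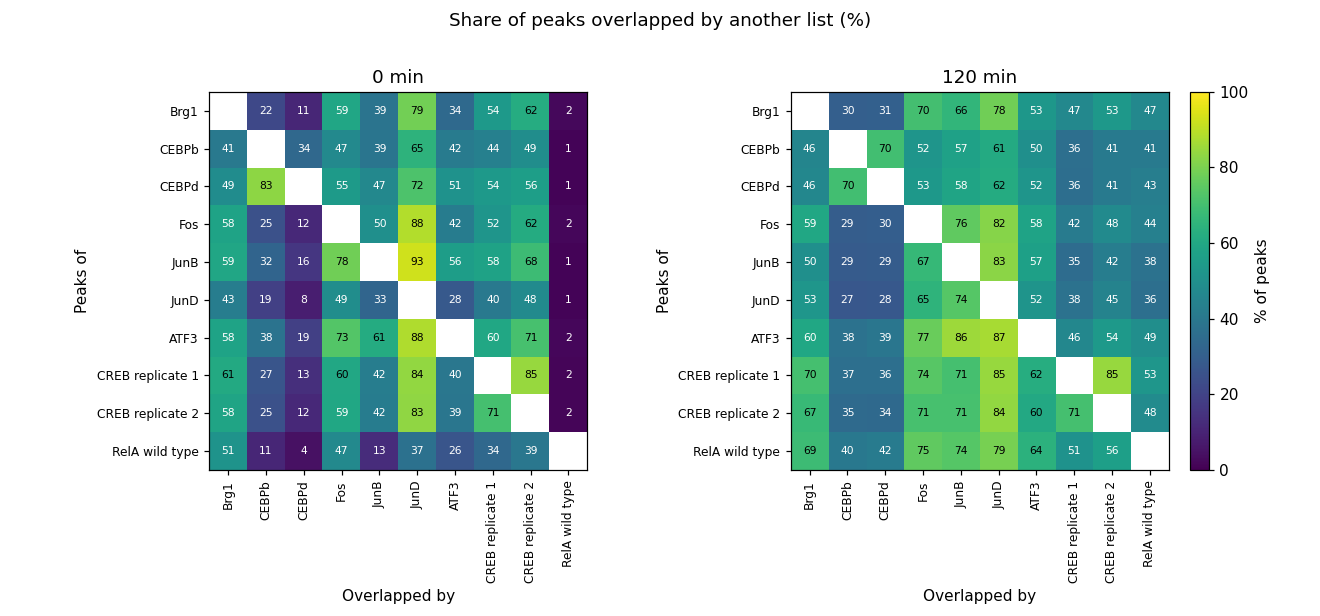
Share of the peaks of each list (rows) overlapped by each other list (columns), in percent, at 0 min (left) and 120 min (right), with colour from 0 to 100 and the rounded share in each cell. The RelA column lies near 0 at 0 min, where RelA had 1476 peaks, and between 36.4% and 52.6% at 120 min.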

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

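TMM scaling, the centred 1.5-fold limit for RelA, the RelA test and its settings, 1 number of top peaks at both times, the order test of CREB overlaps and the fits without 3 CREB libraries were chosen after the data were seen. The alternatives for gene lists and motifs were not run, and centring the medians over time or equalizing peak numbers fixes their outcome. On simulated CREB data 8% of 2-fold changes were recovered at the real depth and at 50% of it, and 16% at 4 times the depth, with the dispersions held. With the stricter score the ratio of peak numbers, 120 over 0 min, became 5.85 for CEBPd, 5.52 for JunB, 248 for RelA in wild type, 60.9 for RelA in IRF3 KO and 0.951 for JunD, which turned its direction; the other 6 ratios stayed within 1.5 times. The RelA ratios rest on few peaks of 0 min. Wild type RelA peaks shared at 15, 30, 60 and 120 min were 79.6%, 87.8%, 79.3% and 80.1% with the stricter score. They were 63.4%, 76.1%, 69.0% and 65.9% by centres within 100 bp, and 68.6%, 80.5%, 72.7% and 70.4% by 50% of each peak. Equal numbers of peaks gave 73.2%, 78.1% and 78.0% at 15, 30 and 60 min. RelA sites higher in IRF3 KO numbered 8 with the stricter score, 11 centred, 112 at 1.5-fold and 43 at 1.5-fold centred. Lower sites numbered 17 centred, 21 at 1.5-fold, 63 at 1.5-fold centred and 4 with equal numbers. Sites called only in wild type numbered 2019 with the stricter score and 2102 with equal numbers, and only in IRF3 KO 2561 and 1706. The cause was not tested for these differences.

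Sites past the RelA genotype test, 3001 as scaled by library size, numbered 1430 centred on library medians and 1133 quantile normalized, and 390 to 3168 without both libraries of 1 time. At the 272 sites called at all 5 times, 30 passed for genotype and 266 for time. The other settings stayed within 1.5 times. The cause was not tested.

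CREB sites past the threshold, 0 in the unblocked edgeR test, numbered 611 with the replicate block, 182 with TMM scaling, 184 centred on library medians, 1432 with TMM scaling and the replicate block, 435 with DESeq2 and 230 with quantile normalized values in limma. Without replicate 2 at 0, 15 and 30 min they numbered 2606, and 2057 with TMM scaling as well. The other alternatives gave 0, including each fit without 1 library, in which the lone library of its time is assumed to vary like the others. The correlations behind the pairing ran from -0.05 to 0.55, with 8 of 10 over 0.1, so that by the rule of over 0.1 in every pair the numbers were not taken as pairs. Among the sites past 0.05 with the block, 26.8% had their largest change upwards as scaled by library size, against 67.4% with TMM scaling and the block. The mean overlap of CREB replicates was 70.7% by centres within 100 bp, 75.5% by 50% of each peak, 82.0% with the stricter score and 81.0% with equal numbers.

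For co-binding at 120 min with the stricter score, centres within 100 bp and 50% of each peak, CEBPd peaks shared with CEBPb were 87.8%, 66.7% and 68.4%. JunB peaks shared with Fos were 40.5%, 60.2% and 63.9%, and 76.6% with equal numbers. ATF3 peaks shared with JunD were 91.4%, 80.2% and 83.9%, and 77.6% with equal numbers. RelA peaks shared with Brg1 were 61.4%, 53.1% and 62.3%, and 60.3% with equal numbers. With 1 number of top peaks at both times the 4 shares were 80.9%, 77.0%, 79.2% and 28.9%, the last of 1476 peaks. The cause was not tested. At 0 min CEBPb and CEBPd shared 0% by 50% of each peak, since the most common widths of 362 and 178 bp rule it out. Chance shares expected from the bases covered stayed at or under the highest of the 100 shifts for these 4 pairs.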

Other observations

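Most wild type RelA peaks called at 60 min and not at 0 min lay at places with a peak of another factor at 0 min. Of 42839 wild type RelA peaks at 60 min that were not called at 0 min, 75.9% (95% interval 75.5 to 76.3) overlapped a peak of at least 1 of the other 8 factors at 0 min, against a mean of 2.58% after 100 random shifts. JunD overlapped 66.7% (66.2 to 67.1) of them, Fos 51.3%, CREB 42.4% in replicate 1 and 49.3% in replicate 2, Brg1 45.0%, JunB 36.9%, ATF3 33.3%, CEBPb 21.9% and CEBPd 10.2%, where random shifts gave means of at most 1.68% for each list. Such shifts cannot part these overlaps from regions where peaks of any factor are frequent. The highest quartile of these RelA peaks by tags overlapped Brg1 of 0 min in 53.4% (52.4 to 54.3) and the lowest quartile in 28.5% (27.6 to 29.3). For JunD the shares were 73.4% (72.6 to 74.3) and 56.4% (55.4 to 57.3).

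For other factors the share of later peaks with a peak of a related factor at 0 min ran from 3.11% to 57.7%. Of 22566 ATF3 peaks at 120 min not called at 0 min, 57.7% (57.0 to 58.3) overlapped JunD of 0 min. Of 40129 JunB peaks at 120 min not called at 0 min, 55.7% (55.3 to 56.2) overlapped JunD of 0 min, and 24.4% overlapped Fos. Of 23388 such CEBPd peaks, 33.7% (33.1 to 34.3) overlapped CEBPb of 0 min, against 90.2% (89.5 to 90.9) of the 6976 CEBPd peaks already called at 0 min. Of 13797 CEBPb peaks called at 120 min and not at 0 min, 3.11% (2.83 to 3.41) overlapped CEBPd of 0 min. The 0 min lists held 19558 CEBPb and 7936 CEBPd peaks, which bears on these C/EBP shares. Peaks of 120 min already called at 0 min had higher shares for the other factors too. With JunD of 0 min the share was 93.6% of 17937 for ATF3 and 97.6% of 20613 for JunB. For JunB with Fos it was 84.2%, and for CEBPb with CEBPd 38.3% of 16630.

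In the 3 patterns that follow, the tests of linkage to chromosome 7, of moved peak centres, of depth and of immunoprecipitation yield were chosen after the results were seen. JunB had more peaks and more tags at 120 min than at 0 min. Deeper sequencing is argued against as the whole cause: at 10 or more tags per 10 M in both lists the ratio of peak numbers was still 3.80. A higher yield of the immunoprecipitation cannot be told apart: 15.1% of 11470 sites with 50 or more tags lay 2-fold or more from the median change, against at most 3.47% between CREB replicates of a time, but JunB had 1 library per time and the spread of its own replicates is not known. A change in JunB binding with stimulation stays open too and was not tested.

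The RelA sites called in 1 genotype only may be weak sites near the calling threshold: their median highest value of 15.5 tags per 10 M lay under 50% of the 46.0 at sites called in both. The tallest of the sites called in 1 genotype only, with 592.3 tags in IRF3 KO and 281.7 in wild type, lay far above 46.0. Both lacked a call at 15 and 120 min in their own genotype as well. Moved or split peak centres were argued against as the cause at most of these sites, although some of the tallest named sites over time had such neighbours. A peak of the other genotype was centred within 1 kb of 7.05% of the 8269 sites, against a mean of 3.88% after random shifts. The highest shift gave 4.39%, so that moved centres at a part of the sites stay open. The tall sites were not tested on their own. The different control libraries of the genotypes stay open as a source and were not tested. A difference between the genotypes at part of these sites stays open and was not tested.

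The 25 RelA sites at least 2-fold apart at all 4 stimulated times could reflect DNA that differs between the genotypes apart from Irf3. Linkage to the Irf3 gene on chromosome 7 is argued against as the whole cause, because 20 of the 25 lay on other chromosomes. Differences in DNA sequence on those chromosomes were not tested and stay open. The 5 on chromosome 7 were all higher in IRF3 KO, 27.8% of 18 sites, where 5.55% of tested sites lay on that chromosome (two-sided Fisher's exact test, p = 0.00242 for this chromosome alone). At the limit of 1.5-fold, 16 of 112 higher sites lay on it, or 14.3% (two-sided Fisher's exact test, p = 0.000440). Of the 21 lower sites at that limit 1 did. A difference in DNA copy number cannot be told apart: pooled control tags differed by a log2 ratio of 0.33 in the direction of RelA (95% interval -0.00401 to 0.669, on about 304 tags). That interval lies below the log2 ratio of 1 that a copy number difference needed as the whole cause, and reaches above the 0.5 set beforehand as the bound against it. An effect of IRF3 itself stays open and was not tested.

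The RelA genotype test passed 3001 sites in the real split of the 8 stimulated libraries. Swapping genotypes within times gives 8 splits, 1 of which reached that number, and the highest of the others passed 15. The splits are too few for a share under 0.05.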
